A study of Mus musculus with 21 samples.

How the data were processed

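Gene expression was measured in 21 mouse libraries: 6 of cultured cardiac fibroblasts and 15 of heart tissue. Groups came from the labels alone: co-cultured fibroblasts (3), fibroblasts alone (3), sham (3), MI (4), MI plus FAPI (4) and MI with Fap knockout (4). Libraries were made with a modified Smart-seq2 protocol with molecular barcodes, per the labels' protocols. Fibroblast libraries started from polyadenylated RNA and were read as 150 bp pairs, and heart libraries started from total RNA, per the labels' protocols. Reads were aligned to mm10 with STAR and counted per gene with HTSeq, with versions not given, per the submitters' processing notes. The deposited values of each library are whole counts per gene. Names of the deposited fibroblast files carry a mark of duplicate removal and those of the heart files do not, and the step is not described in the sources used here. The 2 experiments were therefore never compared with each other.

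The count tables held 53801 gene identifiers, 53620 of which matched a symbol in GENCODE M21, and 0 entries that name no gene. A series-wide table with 6 columns was not used, because its column names could not be mapped to the labels. Strain, littermate status, inhibitor compound and dose are not given in the sources used here.

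Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept with edgeR's filterByExpr, library sizes were scaled with TMM, and groups were compared with edgeR's quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. All 15 hearts entered one fit with a coefficient per group, and the fibroblasts entered another. The 7 comparisons and most of the other settings described below were written before the data were examined. CPM are TMM-normalised, and errors of group means are SD. Errors of fold changes (SE) are approximate, the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Genes named in the text followed a rule fixed before the data were examined. It covers 8 study genes, up to 10 higher and 10 lower genes per comparison with the largest fold change among called genes of at least 10 CPM whose groups did not overlap, and members of gene lists with the smallest p. Text examples of each list are its 2 members with the smallest p, given where space allowed.

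For the hearts 37 gene lists, and for the fibroblasts 28 of them, were written from general knowledge before the data were examined, and 4 more were added afterwards. Each was tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the data. The fry test, which asks whether the genes of a set move on balance one way and does not compare them with other genes, was a further alternative. Counts of higher and lower members used p-values adjusted over all genes, with those adjusted over the list alone beside them. Levels of a list are the mean log2 CPM of its members in each library, and differences of levels between groups of 4 hearts were tested by exact permutation over 70 assignments.

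For the overlap of inhibitor and knockout changes, which share their MI hearts, 20 sets of unchanged groups were simulated. They gave the level that shared hearts produce when each gene varies independently of the others. The MI hearts were also split into 2 and 2 so that each comparison had its own. Alternatives fixed in advance were RLE size factors, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, removal of mitochondrial and the 50 most abundant genes, an absolute log2 fold change of at least 1, each library left out in turn, fits of only the 2 groups compared, and the cardiomyocyte marker level as a covariate. Total-count scaling, removal of trends with GC content and transcript length, fibroblast libraries thinned to 4735337 counts, and the macrophage marker level as a covariate for the interferon response genes were chosen after the data were seen.

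The test was tested on simulated data with known changes. In fibroblast libraries it recovered 4.5%, 47.0% and 87.9% of genes changed 1.5-fold, 2-fold and 4-fold, with 10 false calls among 11921 genes. In knockout against MI hearts it recovered 26.9%, 83.6% and 97.0%, with 6 false calls among 16691 genes. No pair of replicates was a copy of another (chi-square per degree of freedom 3.17 to 207). The TMM factors were 0.626 to 0.697 in sham, 1.24 to 1.55 in MI, 0.929 to 1.14 in inhibitor and 0.888 to 0.986 in knockout hearts. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.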

Results

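The series holds 21 mouse RNA-seq libraries from 2 experiments. In the heart experiment, 15 libraries, called hearts below, were made at day 7 from tissue labelled border zone (the muscle next to an infarct). They were 3 after a sham operation, 4 after myocardial infarction (MI), 4 labelled MI plus FAPI and 4 with MI and a Fap knockout genotype. Fap encodes fibroblast activation protein, a membrane serine protease of activated fibroblasts. FAPI is read here as a Fap inhibitor from the series title, and the compound and dose are not given in the sources used here. In the culture experiment, mouse cardiac fibroblasts were grown for 7 days in 5% GelMA, a gelatin-based hydrogel. They were grown alone in 3 libraries and together with cardiac and lung endothelial cells at a ratio of 2:1 in 3 libraries, and the labels do not say which cell type is the larger part. Fibroblasts from co-culture were sorted as Pdgfra-positive cells without the leukocyte marker CD45 or the endothelial marker CD31. Fibroblasts grown alone were extracted without a sort, so the partner cells and the sort changed together.

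Heart libraries held 18474138 to 37287355 gene counts each: 20827206 to 25943873 in sham, 18474138 to 25927151 in MI, 25798766 to 37287355 in inhibitor and 24519009 to 30571068 in knockout hearts. Fibroblast libraries held 4735337 to 6346015 counts in co-culture and 12871240 to 15650221 alone, with 15880 to 16587 and 19632 to 21807 genes detected. Low genes were therefore measured with less precision in co-culture. The labels call the fibroblast libraries biological replicates and do not say that each heart library is its own animal, so p-values measure the spread between these samples.

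Heart libraries separated by group on the first principal component of 1000 genes, which held 69% of their variance. Its scores ran from 45.0 to 54.9 in sham, 5.05 to 22.7 in knockout, −17.7 to 2.32 in inhibitor and −49.7 to −35.2 in MI hearts. The mitochondrially encoded share of counts followed the same order of group means, at 17.0% ± 2.29 in sham (SD, n = 3), 13.7% ± 0.526 in knockout, 12% ± 1.16 in inhibitor and 5.60% ± 1.68 in MI hearts (SD, n = 4 each). The mean log2 CPM (read counts scaled to library size) of 21 cardiomyocyte markers was 11.2 ± 0.0624 in sham, 10.5 ± 0.137 in knockout, 10.1 ± 0.399 in inhibitor and 8.39 ± 0.643 in MI hearts. The macrophage marker level was 4.80 ± 0.167, 5.57 ± 0.288, 6.17 ± 0.316 and 6.67 ± 0.195 in the same groups. Endothelial markers lay within 4.27 to 4.49 in the 4 group means.

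**Figure D1:**
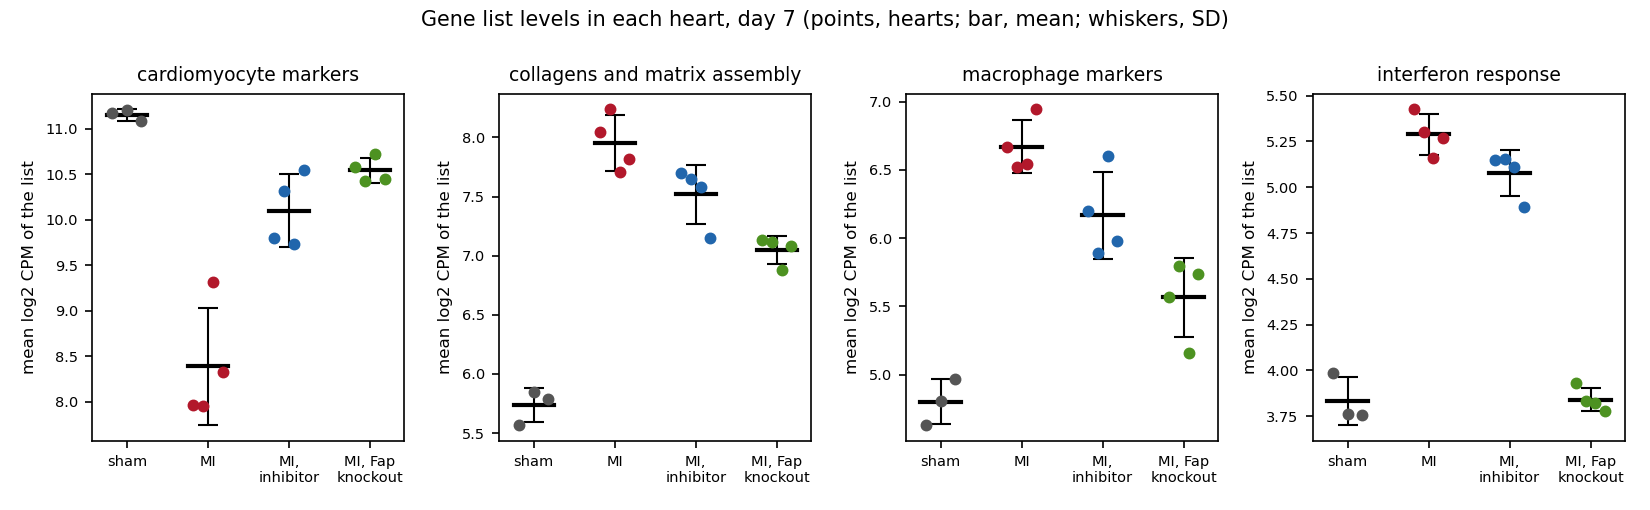
Mean log2 CPM of 4 gene lists (y axes, which do not start at 0) in each heart at day 7, by group (x axes). Points are hearts, bars are means and whiskers are SD, with n = 3 for sham and n = 4 for the other groups. Cardiomyocyte markers average 11.2 in sham and 8.39 in MI hearts, and interferon response genes average 3.84 in knockout and 5.29 in MI hearts.

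Fap (ENSMUSG00000000392.17, mm10 chromosome 2, 62500943 to 62574075, minus strand) was low in every knockout heart. Its counts were 51, 68, 64 and 46 in the 4 knockout hearts, or 2.19, 2.32, 2.36 and 1.79 CPM. Fap averaged 2.16 ± 0.257 CPM in knockout, 3.32 ± 0.578 in sham, 8.26 ± 1.65 in inhibitor and 11.2 ± 1.57 in MI hearts (SD, n = 4, and n = 3 for sham). Counts were given per whole gene, so the remaining ones cannot be placed inside or outside a deleted part. Against MI hearts, Fap fell by 2.36 on the log2 scale in knockout hearts (SE 0.163, adjusted p = 6.94e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

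Knockout hearts lay below sham for Fap, with a log2 fold change of −0.61 (SE 0.193, edgeR adjusted p = 0.0197). This call ended without sham replicate 2 (−0.59, adjusted p = 0.0586), sham replicate 3 (−0.49, 0.0937) or knockout replicate 4 (−0.53, 0.0547) and with limma-voom (−0.60), and total-count scaling nearly removed the difference (−0.08, 0.79). The adjusted p ranged from 0.00459 to 0.79 over 19 settings. Dpp4, the serine peptidase gene next to Fap (chromosome 2, 62330073 to 62412231), was also lower in knockout than in MI hearts (log2 fold change −1.01, SE 0.313, edgeR adjusted p = 0.0133). Its mean was 1.11 ± 0.433 CPM in knockout and 2.25 ± 0.521 CPM in MI hearts. The Dpp4 call was lost when the cardiomyocyte marker level entered the model (−0.70, adjusted p = 0.837), and the adjusted p ranged from 0.000767 to 0.837 over 20 settings.

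**Figure D2:**
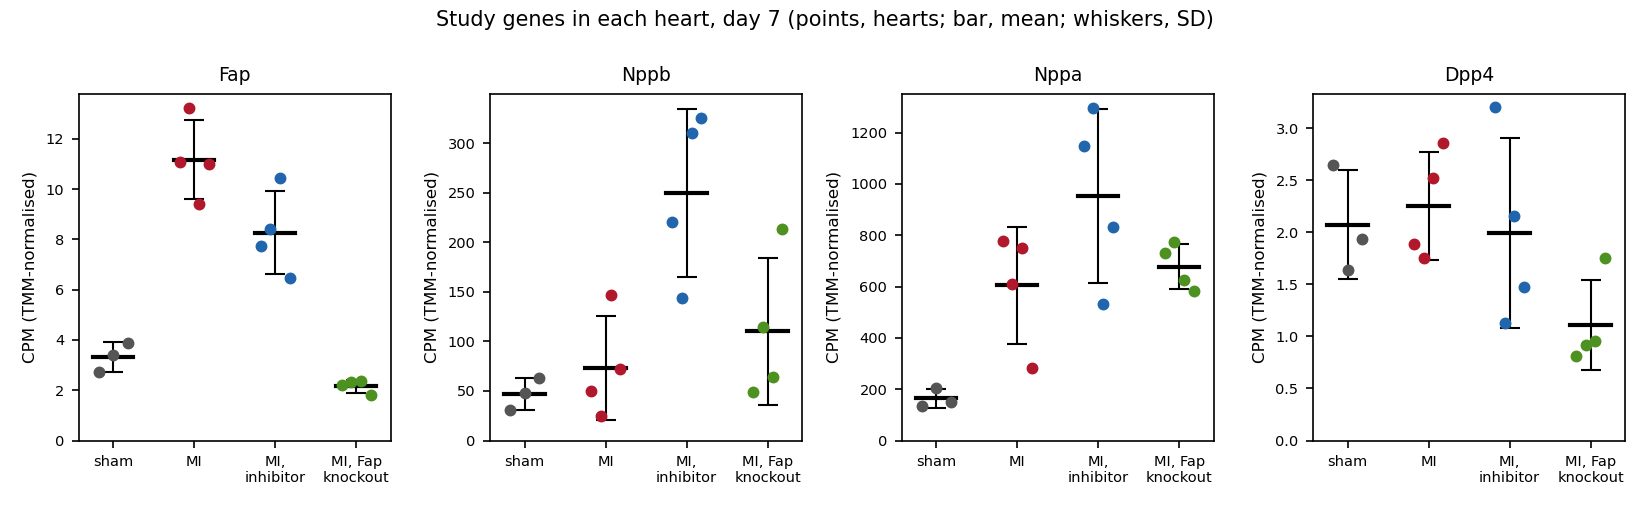
TMM-normalised CPM (y axes) of Fap, Nppb, Nppa and Dpp4 in each heart at day 7, by group (x axes). Points are hearts, bars are means and whiskers are SD, with n = 3 for sham and n = 4 for the other groups. Fap averages 11.2 CPM in MI and 2.16 CPM in knockout hearts, and Nppb averages 73.4 CPM in MI and 249.7 CPM in inhibitor hearts.

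The comparison of MI with sham hearts addresses how infarcted and sham-operated hearts differed at day 7. MI hearts held more RNA of extracellular matrix and immune genes and less of cardiomyocyte and energy metabolism genes (n = 4 and 3). All 28 genes of collagens and matrix assembly rose, with a median log2 fold change of 2.42, and 28 adjusted over the list alone. Examples were Col5a2, a fibrillar collagen chain (2.77, SE 0.15), and Bgn, the small proteoglycan biglycan (2.57, SE 0.152). The camera adjusted p was 7.17e-20, and adjusted p = 0.113 with an estimated correlation. All 22 activated fibroblast markers rose as well (median 2.61, 22 adjusted over the list alone, camera adjusted p = 3.16e-12, adjusted p = 0.113 with an estimated correlation). Ltbp2, a matrix protein, rose by 2.71 (SE 0.146) and Sfrp1, a secreted Wnt antagonist, by 2.90 (SE 0.222).

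Immune genes rose in the same hearts. Of 23 macrophage markers, 20 rose and 3 did not pass the test, with a median log2 fold change of 2.16 and 20 adjusted over the list alone. Fcgr1, the high-affinity IgG receptor, rose by 2.53 (SE 0.166) and Adgre1, the macrophage surface receptor, by 2.16 (SE 0.171). The list had a camera adjusted p of 1.14e-08, and adjusted p = 0.19 with an estimated correlation. All 11 neutrophil markers rose (median 3.34, 11 adjusted over the list alone, camera adjusted p = 0.0151, adjusted p = 0.415 with an estimated correlation), among them the granulocyte colony-stimulating factor receptor gene Csf3r (2.86, SE 0.306). The calgranulin genes S100a8 and S100a9 rose by 3.43 (SE 0.548) and 3.51 (SE 0.586). All 24 interferon response genes rose (median 1.5, 24 adjusted over the list alone, camera adjusted p = 2.59e-12, adjusted p = 0.113 with an estimated correlation). Irf7, a transcription factor of the interferon response, rose by 2.13 (SE 0.121) and Ifi44, an interferon-induced gene, by 1.83 (SE 0.119).

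Genes of the heart muscle cell and its mitochondria fell after MI. All 21 cardiomyocyte markers fell (median log2 fold change −2.54, 21 adjusted over the list alone), including Pln, the calcium pump inhibitor phospholamban (−3.58, SE 0.215), and Ckm, muscle creatine kinase (−3.60, SE 0.249). Camera gave adjusted p = 6.1e-10, and adjusted p = 0.257 with an estimated correlation. All 25 fatty acid oxidation genes tested fell (median −3.09, 25 adjusted over the list alone, camera adjusted p = 4.61e-22, adjusted p = 0.113 with an estimated correlation), with Hadh at −3.37 (SE 0.185) and Eci1 at −3.69 (SE 0.217). All 40 nuclear genes of oxidative phosphorylation fell (median −2.97, 40 adjusted over the list alone, camera adjusted p = 3.05e-28, adjusted p = 0.161 with an estimated correlation), with the complex I gene Ndufs1 at −2.97 (SE 0.201). Among the genes with the lowest ratios were the water channel gene Aqp4 (15.2 ± 4.27 CPM in sham, 0.307 ± 0.0865 in MI hearts), the muscle fructose-bisphosphatase gene Fbp2 (79.0 ± 14.8 and 2.05 ± 0.329) and the potassium channel partner gene Kcnip2 (57.7 ± 4.40 and 2.40 ± 0.87).

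Of the genes the study is about, Fap rose by 1.75 after MI (SE 0.181, adjusted p = 3.09e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Nppa, which encodes atrial natriuretic peptide, rose by 1.89 (SE 0.329, edgeR adjusted p = 8.67e-05). Nppb, which encodes B-type natriuretic peptide (BNP; ENSMUSG00000029019.8, chromosome 4, 147985788 to 147987205), averaged 73.4 ± 52.4 CPM in MI and 47.3 ± 16.1 in sham hearts, a log2 difference of 0.63 that did not pass the test (SE 0.529, edgeR adjusted p = 0.295). The difference rested on MI replicate 3 (146.6 CPM, others 25.2 to 71.9) and was 0.05 without it (adjusted p = 0.927). With total-count scaling Nppb passed (1.64, adjusted p = 0.00851, range over 19 settings 0.00851 to 0.927). With the cardiomyocyte marker level as a covariate it was 2.68 (SE 1.18) and did not pass (edgeR adjusted p = 0.181). Mme, the natriuretic peptide-degrading protease neprilysin, fell by 1.14 (SE 0.268, edgeR adjusted p = 0.00124), but not past the test with total-count scaling (−0.05, adjusted p = 0.868, range over 19 settings 9.81e-05 to 0.868). In the natriuretic peptide and cGMP signalling list, 6 of 15 genes rose, 4 fell and 5 did not pass, with 6 and 4 adjusted over the list alone (median 0.38, camera adjusted p = 0.437). The soluble guanylate cyclase genes Gucy1b1 (1.20, SE 0.137) and Gucy1a1 (1.95, SE 0.238) were among the higher ones.

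Sham hearts alone lay at least 4-fold apart from every other heart in 18 genes, among them a nuclear copy of a mitochondrial gene. A difference of stock or handling beside the operation is therefore not excluded for any comparison with sham or for the return toward sham. In all, 11783 of 17064 genes tested differed between MI and sham hearts (6331 higher, 5452 lower, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The groups did not overlap for 67.5% of genes, where chance gives 5.71%. TMM normalisation placed the median log2 fold change of all genes at 0.14 and total-count scaling at 1.23, so directions here are relative to the TMM reference. The share of called genes that were higher was 53.7% with TMM and 86.1% with total-count scaling. With the cardiomyocyte marker level of each heart as a covariate, 1292 genes were called (818 higher, 474 lower). Fap (0.83, adjusted p = 0.207, range over 19 settings 1.32e-15 to 0.207), Nppa (2.40, adjusted p = 0.0772, range 1.3e-09 to 0.0772), Mme (−1.24, adjusted p = 0.38) and Gucy1a1 were no longer past the threshold.

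The comparison of inhibitor-treated with untreated MI hearts addresses what the inhibitor changed after infarction (n = 4 each). Inhibitor hearts held more RNA of cardiomyocyte and mitochondrial genes and less of neutrophil, B cell and adipocyte markers. All 21 cardiomyocyte markers were higher (median log2 fold change 1.70, 21 adjusted over the list alone), among them Pln (1.47, SE 0.193) and the myoglobin gene Mb (2.16, SE 0.283). The camera adjusted p was 1.59e-19, and adjusted p = 0.197 with an estimated correlation. All 40 oxidative phosphorylation genes were higher (median 1.38, 40 adjusted over the list alone, camera adjusted p = 5.74e-37, adjusted p = 0.197 with an estimated correlation), as in Uqcrc2 of complex III (1.80, SE 0.222) and Cox8b of complex IV (2.07, SE 0.272). Of 25 fatty acid oxidation genes 24 were higher and 1 did not pass (median 1.21, 24 adjusted over the list alone, camera adjusted p = 1.98e-23, adjusted p = 0.197 with an estimated correlation). Ppara, the transcription factor that controls them, was higher by 1.92 (SE 0.224) and the electron transfer gene Etfdh by 1.63 (SE 0.215).

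Cardiomyocyte stress genes were also higher in inhibitor hearts, 10 of 14 past the test and 4 not (median 1.55, 13 adjusted over the list alone, camera adjusted p = 4.9e-08, adjusted p = 0.197 with an estimated correlation). Acta1, skeletal muscle actin, was 6.73-fold higher (3466 ± 1155 against 515 ± 259 CPM) and Ankrd1, a stress-induced sarcomere protein, 3.09-fold. The ketone-metabolising enzyme gene Bdh1 was 7.07-fold higher (33.3 ± 12 against 4.71 ± 3.07 CPM). Nppb was 3.41-fold higher, at 249.7 ± 84.6 against 73.4 ± 52.4 CPM (log2 fold change 1.77, SE 0.491, adjusted p = 0.0129, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and stayed past the threshold without any 1 of the 8 hearts (2.35 without MI replicate 3). Nppa did not pass (0.65, SE 0.287, edgeR adjusted p = 0.0979), except without inhibitor replicate 3 (0.85, adjusted p = 0.0265) and with no filter on low counts (0.66, 0.0229), with a range over 20 settings of 0.0229 to 0.981. Mme did not pass either (−0.67, SE 0.263, edgeR adjusted p = 0.0641), except without MI replicate 4 (−0.78, adjusted p = 0.0485), inhibitor replicate 2 (−0.83, 0.0477) or inhibitor replicate 3 (−0.80, 0.0481) and with total-count scaling (−1.10, 0.00557), with a range over 20 settings of 0.00557 to 0.938.

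Fap itself was lower in inhibitor than in MI hearts by a log2 fold change of −0.44 (SE 0.145, adjusted p = 0.0328, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the groups overlapped. The call was lost without any 1 of 6 hearts: MI replicate 1 (−0.44, adjusted p = 0.0569), MI replicate 2 (−0.34, 0.11), MI replicate 4 (−0.45, 0.0546), inhibitor replicate 1 (−0.41, 0.0725), inhibitor replicate 2 (−0.45, 0.0604) or inhibitor replicate 4 (−0.33, 0.117). With the cardiomyocyte marker level as a covariate Fap did not differ past the test and was positive (0.13, 0.981). The adjusted p ranged from 0.00239 to 0.981 over 20 settings.

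Of 28 genes of collagens and matrix assembly, 11 were lower in inhibitor hearts and 17 did not pass, with 11 adjusted over the list alone and 26 lower with total-count scaling. The median was −0.37 (camera adjusted p = 1.6e-05, adjusted p = 0.338 with an estimated correlation), with Col5a1 at −0.72 (SE 0.168) and Col1a2 at −0.80 (SE 0.191). Neutrophil markers were lower in 9 of 11 and did not pass in 2 (median −1.87, 10 adjusted over the list alone, camera adjusted p = 8.63e-05, adjusted p = 0.197 with an estimated correlation). S100a8 was lower by −3.29 (SE 0.481), and so were the granule protein genes Ngp (−4.10, SE 0.703) and Camp (−3.91, SE 0.72), which were −2.71 and −2.45 without MI replicate 2. B cell markers were lower in 9 of 10 and did not pass in 1 (median −2.11, 9 adjusted over the list alone, camera adjusted p = 0.00013, adjusted p = 0.252 with an estimated correlation), as in Cd79b of the B cell receptor (−1.36, SE 0.26). Adipocyte markers were lower in 7 of 10, higher in 1 and did not pass in 2 (median −3.17, 7 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.000157, adjusted p = 0.197 with an estimated correlation). The lipid droplet gene Plin1 averaged 0.925 ± 0.454 CPM against 10.5 ± 2.72, and the adipocyte hormone gene Retn 8.77 ± 7.27 against 99.3 ± 35.6, a log2 fold change of −3.49 that was −4.21 without inhibitor replicate 3. Of 23 macrophage markers 10 were lower and 13 did not pass (median −0.59, 12 adjusted over the list alone, camera adjusted p = 3.44e-05, adjusted p = 0.29 with an estimated correlation), and their level per heart did not pass (−0.502, exact permutation p = 0.0857).

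The test called 5081 of 17064 genes between inhibitor and MI hearts (3053 higher, 2028 lower), and the groups did not overlap for 26.1% of genes, where chance gives 2.86%. Total-count scaling called 9933 genes and moved the share that were higher from 60.1% to 14.6%. Without inhibitor replicate 4, 3359 genes were called. The cardiomyocyte marker level differed between these groups by 1.71, and with it as a covariate 30 genes were called, 25 of them among the 5081. Of 40 genes named by the fixed rule, 30 then lost the call in the same direction, Nppb among them (0.60, adjusted p = 0.978, range over 20 settings 9.3e-06 to 0.978). Pln and Mb, also among the 30, belong to the marker list behind the covariate, so their loss was partly built in. The adipocyte genes among the 30 had lower precision rather than a much smaller fold change, as in Plin1 (−3.04, SE 0.71, from −3.48, SE 0.435) and Retn (−3.30, SE 0.925, from −3.49, SE 0.599). Another 5 of the 40 changed sign. These were Fap and Col5a1, called without the covariate, and Npr2, Npr3 and Dpp4, called in neither fit.

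The comparison of knockout with wild-type MI hearts addresses how Fap knockout and wild-type hearts differed after infarction (n = 4 each). No knockout heart without infarction was in the series, so differences already present before infarction cannot be told apart from a changed response to it. All 24 interferon response genes fell in knockout hearts, with a median log2 fold change of −1.44 and 24 adjusted over the list alone. Irf7 fell by 2.11 (SE 0.108, adjusted p = 5.28e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Ifi44 by 1.71 (SE 0.103, edgeR adjusted p = 2.96e-08). The camera adjusted p was 4.85e-32, and adjusted p = 0.0348 with an estimated correlation. Of 23 macrophage markers 20 fell and 3 did not pass (median −1.26, 20 adjusted over the list alone, camera adjusted p = 1.01e-08, adjusted p = 0.168 with an estimated correlation). Fcgr1 fell by 1.91 (SE 0.141) and Fcer1g, an Fc receptor signalling chain, by 1.60 (SE 0.165). The monocyte-expressed genes Ms4a4c and Plac8 dropped to 10.5 ± 0.45 from 76.8 ± 9.21 CPM and to 22.6 ± 4.76 from 139 ± 11.8 CPM.

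Matrix genes fell in the same hearts. Of 28 genes of collagens and matrix assembly 24 fell and 4 did not pass (median −0.90, 25 adjusted over the list alone, camera adjusted p = 2.27e-09, adjusted p = 0.247 with an estimated correlation). Col5a2 fell by 1.19 (SE 0.127) and Loxl3, a collagen-crosslinking oxidase, by 1.44 (SE 0.154). Activated fibroblast markers fell in 19 of 22, rose in 1 and did not pass in 2 (median −1.15, 19 lower and 1 higher adjusted over the list alone, camera adjusted p = 2.28e-07, adjusted p = 0.168 with an estimated correlation). Fap is itself a member of that list, and Ltbp2 fell by 0.99 (SE 0.122).

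Energy metabolism and cardiomyocyte genes were higher in knockout hearts. All 25 fatty acid oxidation genes rose (median 2.14, 25 adjusted over the list alone, camera adjusted p = 9.29e-30, adjusted p = 0.137 with an estimated correlation). Ucp3, a mitochondrial carrier, rose to 10.9 ± 1.17 from 0.681 ± 0.11 CPM and Hadh by 2.16 (SE 0.171). All 40 oxidative phosphorylation genes rose (median 1.91, 40 adjusted over the list alone, camera adjusted p = 8.01e-32, adjusted p = 0.16 with an estimated correlation), with Cox7a1 at 2.99 (SE 0.278) and Cox8b at 2.75 (SE 0.279). All 21 cardiomyocyte markers rose (median 2.01, 21 adjusted over the list alone, camera adjusted p = 1.36e-14, adjusted p = 0.168 with an estimated correlation), with Pln at 2.27 (SE 0.198) and Ckm at 2.63 (SE 0.232). The lipid droplet gene Plin5 rose 12.8-fold, to 136 ± 34.6 from 10.6 ± 3.70 CPM, and Fbp2 rose 12-fold, to 24.5 ± 3.50 from 2.05 ± 0.329 CPM.

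Nppb averaged 110.3 ± 74.2 CPM in knockout and 73.4 ± 52.4 CPM in MI hearts and did not pass the test (0.59, SE 0.48, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.322). Its direction depended on the setting: without MI replicate 3 the difference passed (1.17, adjusted p = 0.0401), and with the cardiomyocyte marker level as a covariate it was negative and did not pass (−0.93, 0.838), with a range over 20 settings of 0.0401 to 0.939. Nppa did not pass (0.16, SE 0.286, edgeR adjusted p = 0.656) and was also negative with the covariate (−0.24). Mme was higher by 0.74 (SE 0.243, edgeR adjusted p = 0.0179), a call lost without MI replicate 1 (0.65, adjusted p = 0.0531), MI replicate 4 (0.63, 0.053) or knockout replicate 4 (0.63, 0.0592), with total-count scaling (0.19, 0.537) and with the cardiomyocyte marker level as a covariate (0.82, 0.752), with a range over 20 settings of 0.00647 to 0.752.

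In total 8700 of 17064 genes were called between knockout and MI hearts (4271 higher, 4429 lower), and the groups did not overlap for 45.4% of genes, where chance gives 2.86%. Total-count scaling moved the share of called genes that were higher from 49.1% to 16.6%. The cardiomyocyte marker level differed by 2.15, and with it as a covariate 143 genes were called (14 higher, 129 lower), 125 of them among the 8700. Of 40 genes named by the fixed rule 26 then lost the call, among them Col5a2, Loxl3, Ltbp2, Hadh, Cox7a1, Cox8b and Fcer1g. Pln and Ckm also lost the call, but they belong to the marker list behind the covariate, so this was partly built in. Ucp3 (3.13, SE 0.803), S100a9 (−3.95, SE 0.905) and S100a8 (−3.72, SE 0.866) lost it with larger errors and fold changes still past 8-fold. Fap (−1.64), Irf7 (−1.87), Ifi44 (−1.23), Fcgr1 (−1.44), Ms4a4c (−3.07), Plac8 (−2.03), Plin5 (1.77) and Fbp2 (2.20) stayed past the threshold.

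Inhibitor and knockout hearts were compared directly to find where the 2 interventions differed (n = 4 each). All 24 interferon response genes were higher in inhibitor hearts, by a median log2 fold change of 1.20, with 24 adjusted over the list alone. Irf7 averaged 97.8 ± 13.4 CPM in inhibitor and 27.5 ± 2.44 in knockout hearts (1.83, SE 0.107, adjusted p = 6.34e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Ifit1, an antiviral RNA-binding protein gene, 77.3 ± 11.9 and 22.3 ± 1.95, and the nucleic acid sensor gene Zbp1 32.9 ± 2.04 and 9.92 ± 1.04. The camera adjusted p was 2.27e-79, and adjusted p = 0.000736 with an estimated correlation. Among the lists fixed before the data were examined, only interferon response held its call with an estimated correlation, in this comparison and in knockout against MI hearts. The macrophage marker level was higher in inhibitor hearts as well, by 0.601 (2-sided exact permutation p = 0.0286, the smallest that 4 against 4 allow).

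Activated fibroblast markers were higher in inhibitor than in knockout hearts in 12 of 22, and 10 did not pass (median 0.69, 16 adjusted over the list alone, camera adjusted p = 7.91e-12, adjusted p = 0.119 with an estimated correlation). Fap was higher by 1.93 (SE 0.163, edgeR adjusted p = 1.98e-06) and Ltbp2 by 0.71 (SE 0.121). Immediate early genes, which respond within minutes to stimulation, were higher in 11 of 19, and 8 did not pass (median 0.55, 13 adjusted over the list alone, camera adjusted p = 1.98e-07, adjusted p = 0.119 with an estimated correlation). The AP-1 genes Fos (1.5, SE 0.27) and Junb (0.79, SE 0.129) were among them. Fatty acid oxidation genes were lower in 19 of 25, and 6 did not pass (median −0.76, 24 adjusted over the list alone, camera adjusted p = 2.92e-20, adjusted p = 0.139 with an estimated correlation), with Ucp3 at −2.60 (SE 0.278). Acot2, also lower (−1.49, SE 0.205), belongs to a family of similar acyl-CoA thioesterase genes that can share reads. Adipocyte markers were lower in 6 of 10, and 4 did not pass (median −1.59, 8 adjusted over the list alone, camera adjusted p = 7.45e-07, adjusted p = 0.119 with an estimated correlation), among them Fabp4, a fatty acid-binding protein (−1.19, SE 0.149), and Lipe, hormone-sensitive lipase (−0.81, SE 0.131).

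Mme was lower in inhibitor than in knockout hearts, at 0.58 ± 0.198 against 1.55 ± 0.25 CPM (−1.41, SE 0.257, adjusted p = 0.0022, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Nppb did not pass (1.18, SE 0.483, edgeR adjusted p = 0.115), except without knockout replicate 4 (1.72, adjusted p = 0.0334) and with no filter on low counts (1.19, 0.00527), with a range over 20 settings of 0.00527 to 0.279. In this comparison 2247 of 17064 genes were called (1203 higher, 1044 lower), and the groups did not overlap for 18.6% of genes, where chance gives 2.86%. The count was 1352 without inhibitor replicate 1, 1197 without inhibitor replicate 3, 1430 without knockout replicate 1 and 1125 without knockout replicate 3. Total-count scaling moved the share that were higher from 53.5% to 67.9%.

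Against sham hearts, inhibitor hearts were higher in interferon response and matrix genes, and knockout hearts were higher in matrix genes (n = 4 against 3 each). All 24 interferon response genes were higher in inhibitor than in sham hearts (median 1.22, 24 adjusted over the list alone, camera adjusted p = 1.9e-16, adjusted p = 0.0858 with an estimated correlation), with Irf7 at 1.85 (SE 0.12) and Ifi44 at 1.67 (SE 0.119). Between knockout and sham hearts 21 of the 24 did not pass and 3 were lower, with 2 adjusted over the list alone. There the median was 0.06, the mean 0.00 and the camera direction down (adjusted p = 0.925), and total-count scaling called 18 higher and 0 lower. The lower members Irf9, part of the interferon-activated transcription complex (−0.41, SE 0.105), and Gbp3, a guanylate-binding protein (−0.44, SE 0.132), had edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at adjusted p = 0.00606 and 0.0149. Irf9 lost its call without sham replicate 1 (−0.29, adjusted p = 0.056, range over 19 settings 0.000589 to 0.392) and Gbp3 without sham replicate 2 (−0.38, adjusted p = 0.0709, range 0.00138 to 0.624) and with GC and length trends removed (−0.32), and both turned positive with total-count scaling (0.14 and 0.10).

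All 28 genes of collagens and matrix assembly were higher in inhibitor than in sham hearts (median 1.87, 28 adjusted over the list alone, camera adjusted p = 9.84e-25, adjusted p = 0.0858 with an estimated correlation), with Col5a2 at 2.47 (SE 0.148) and Fbn1, the microfibril gene fibrillin, at 2.06 (SE 0.136). In knockout hearts 26 were higher and 2 did not pass (median 1.38, 28 adjusted over the list alone, camera adjusted p = 4.66e-29, adjusted p = 0.0834 with an estimated correlation), with Fbn1 at 1.63 (SE 0.134) and elastin gene Eln at 1.98 (SE 0.167). Macrophage markers against sham were higher in 19 of 23, lower in 1 and not past the test in 3 in inhibitor hearts (median 1.56, 20 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.26e-08, adjusted p = 0.234 with an estimated correlation), with Fcgr1 at 1.93 (SE 0.163) and Adgre1 at 1.70 (SE 0.169). In knockout hearts 15 were higher and 8 did not pass (median 0.76, 17 adjusted over the list alone, camera adjusted p = 7.72e-06, adjusted p = 0.321 with an estimated correlation), with the chemokine receptor genes Cx3cr1 at 1.40 (SE 0.188) and Ccr2 at 2.00 (SE 0.271).

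Oxidative phosphorylation genes were below sham in both groups. All 40 were lower in inhibitor hearts (median −1.59, 40 adjusted over the list alone, camera adjusted p = 4.85e-18, adjusted p = 0.327 with an estimated correlation), with the complex II gene Sdha at −1.76 (SE 0.203). All 40 were lower in knockout hearts too (median −1.05, 40 adjusted over the list alone, camera adjusted p = 9.34e-16, adjusted p = 0.321 with an estimated correlation), with Ndufs1 at −1.24 (SE 0.194). Nppa was above sham in inhibitor hearts (2.54, SE 0.339, adjusted p = 1.33e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and in knockout hearts (2.05, SE 0.331, edgeR adjusted p = 0.000251). Nppb was above sham in inhibitor hearts (2.40, SE 0.564, edgeR adjusted p = 0.00185). In knockout hearts it did not pass (1.22, SE 0.538, edgeR adjusted p = 0.0815). It passed in 5 of 19 settings: without knockout replicate 1 (1.47, adjusted p = 0.0458), with the cardiomyocyte marker level as a covariate (1.75, 0.0278), with only the 2 groups fitted (1.28, 0.0267), with total-count scaling (1.77, 0.0101) and with no filter on low counts (1.27, 0.00343), with a range over 19 settings of 0.00343 to 0.3. The serpin gene Serpinb1c was 9.74-fold above sham in inhibitor and 10.5-fold in knockout hearts, and Aqp4 was below sham in both (−4.47, SE 0.282, and −3.07, SE 0.259).

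The counts of called genes were 9517 for inhibitor against sham (4987 higher, 4530 lower) and 6740 for knockout against sham (3281 higher, 3459 lower). The groups did not overlap for 57.5% and 46.8% of 17064 genes, where chance gives 5.71%. Total-count scaling moved the share that were higher from 52.4% to 86.8% and from 48.7% to 91.7%. It moved the median log2 fold change of all genes to 0.77 and 0.59, from 0.09 and 0.05 with TMM. In the comparisons with MI hearts it moved that median to −0.44 for the inhibitor and −0.63 for the knockout, from −0.03 and −0.08, and between inhibitor and knockout hearts to 0.16 from 0.02.

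The changes from MI hearts were then set side by side, to ask how far inhibitor and knockout moved genes alike. Of the 17064 genes, 2821 were higher in both, where independent lists would share 764, and 1686 were lower in both, where independent lists would share 526. Only 8 were called in opposite directions, against 1300.0 for independent lists. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.827 with a covariance of 0.447. Both comparisons used the same 4 MI hearts, and 20 simulated sets of unchanged groups gave a mean correlation of 0.483 and covariance of 0.0332. In these sets each gene varied independently. Real hearts also vary together across genes, as in the cardiomyocyte marker level (7.95 to 9.32 among MI hearts), so the simulated level can be too low. With the MI hearts split into 2 and 2, so that no heart was shared, the correlation averaged 0.686 over 6 ways (0.642 to 0.757) and the covariance 0.396. The counts then averaged 1874.7 higher in both, 830 lower in both and 17.5 in opposite directions (3 to 48), and the simulated sets gave 0 of each. Cardiomyocyte markers and interferon response genes show both sides of this, the first with medians of 1.70 and 2.01 and the second with medians of −0.24 and −1.44 in inhibitor and knockout hearts. Of the 24 interferon response genes 4 were lower in inhibitor than in MI hearts, with 2 adjusted over the list alone (camera adjusted p = 0.00514, adjusted p = 0.392 with an estimated correlation).

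**Figure D3:**
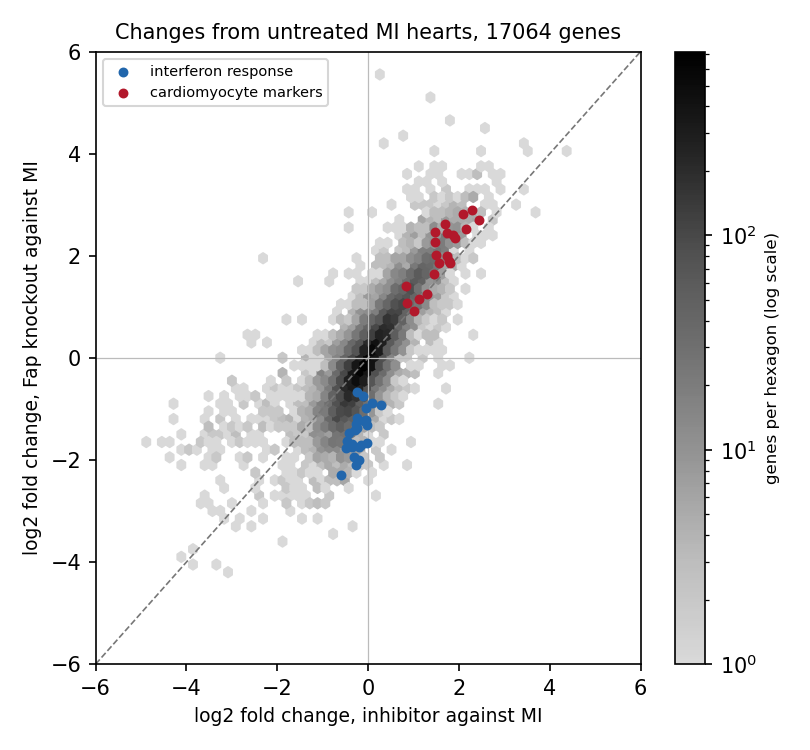
Log2 fold change of 17064 genes against untreated MI hearts, in inhibitor hearts (x axis) and in knockout hearts (y axis). Grey hexagons hold at least 1 gene, darker with more genes on a log scale, points are members of 2 gene lists, and the dashed line marks equal change. Interferon response genes lie at a median of −0.24 on x and −1.44 on y, and cardiomyocyte markers at 1.70 and 2.01.

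Of the 11783 genes that differed between MI and sham hearts, 89.8% moved in the opposite direction in inhibitor hearts and 95.7% in knockout hearts, compared with MI hearts. In simulated unchanged groups that share the MI hearts, 53.3% did so in each. Genes varied independently there, so this level can be too low for hearts that vary together across genes. With separate MI hearts for the 2 comparisons the shares were 86.5% and 93.3%. Genes called in the opposite direction numbered 4601 in inhibitor and 7915 in knockout hearts, and 65 and 37 were called in the same direction as MI. With separate MI hearts these averaged 2998.7 and 6347.2 opposite, and 66.5 and 45.3 in the same direction. The covariance with the change after MI was −0.929 for the inhibitor and −1.5 for the knockout, against −0.0491 and −0.0496 in the simulated sets and −0.916 and −1.52 with separate MI hearts. The series holds no knockout or inhibitor hearts without infarction. A weaker response to MI therefore cannot be told apart from a difference present without it.

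The culture comparison addresses how endothelial partner cells, together with the sort, changed cardiac fibroblasts (n = 3 each). Co-cultured fibroblasts held more RNA of interferon response, complement and resting fibroblast genes and less of cell cycle genes. Of 23 interferon response genes 22 were higher and 1 did not pass (median log2 fold change 3.13, 22 adjusted over the list alone, camera adjusted p = 3.72e-17, adjusted p = 0.203 with an estimated correlation). Bst2, the antiviral protein tetherin, was higher by 3.13 (SE 0.164) and Igtp, an interferon-induced GTPase, by 3.20 (SE 0.172). Complement genes were higher in 10 of 13 and lower in 3 (median 3.13, 10 and 3 adjusted over the list alone, camera adjusted p = 2.39e-08, adjusted p = 0.178 with an estimated correlation), with the C1 inhibitor gene Serping1 at 3.30 (SE 0.127) and the C1 protease gene C1ra at 3.51 (SE 0.158). Antigen presentation genes were higher in 7 of 10, lower in 1 and not past the test in 2 (median 2.02, 7 and 1 adjusted over the list alone, camera adjusted p = 2.53e-06, adjusted p = 0.178 with an estimated correlation), with the immunoproteasome genes Psmb9 at 3.72 (SE 0.159) and Psmb8 at 3.29 (SE 0.179).

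Resting fibroblast markers were higher in 15 of 17 and lower in 2 in co-culture (median 1.82, 15 and 2 adjusted over the list alone, camera adjusted p = 3.71e-10, adjusted p = 0.178 with an estimated correlation). C4b, also a complement gene, was higher by 4.28 (SE 0.194) and Entpd2, an enzyme that splits extracellular ATP, by 3.39 (SE 0.158). Pdgfra, on which only the co-cultured cells were sorted, is in this list, so partner cells and sort cannot be told apart here. Activated fibroblast markers were lower in 12 of 18, higher in 4 and not past the test in 2 (median −0.97, 12 and 4 adjusted over the list alone, camera adjusted p = 0.00228, adjusted p = 0.244 with an estimated correlation), with the secreted matrix-associated protein gene Ccn4 at −2.52 (SE 0.158). All 25 cell cycle genes were lower (median −1.87, 25 adjusted over the list alone, camera adjusted p = 3.72e-17, adjusted p = 0.178 with an estimated correlation), with the mitotic genes Ccnb1 at −1.96 (SE 0.108) and Tpx2 at −2.15 (SE 0.119). Immediate early genes were higher in 12 of 18, lower in 2 and not past the test in 4 (median 1.47, 13 and 2 adjusted over the list alone, camera adjusted p = 6.58e-06, adjusted p = 0.203 with an estimated correlation), with Junb at 3.02 (SE 0.123) and Fos at 3.32 (SE 0.161).

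Markers of other cell types moved with the culture groups as well. The sort kept Pdgfra-positive cells and removed those with CD45 or CD31, in co-culture only. Lower markers of leukocytes, endothelial cells or other cell types, mesothelial ones included, therefore cannot be credited to the partner cells. Macrophage markers were lower in co-culture in 14 of 18, higher in 1 and not past the test in 3 (median −1.71, 14 and 1 adjusted over the list alone, camera adjusted p = 0.000203, adjusted p = 0.214 with an estimated correlation). The complement C1q gene C1qc was lower by −2.12 (SE 0.195), and the transmembrane glycoprotein gene Gpnmb was higher by 2.14 (SE 0.129). Epicardial and mesothelial markers were lower in 7 of 8, and 1 did not pass (median −1.51, 7 adjusted over the list alone, camera adjusted p = 0.000826, adjusted p = 0.178 with an estimated correlation), with the uroplakin genes Upk3b at −2.81 (SE 0.175) and Upk1b at −2.42 (SE 0.184). Endothelial markers were higher in 3 of 10, lower in 2 and not past the test in 5 (median −0.15, 3 and 2 adjusted over the list alone, camera adjusted p = 0.743), with Eng, a transforming growth factor beta co-receptor, at 0.99 (SE 0.106) and the receptor phosphatase gene Ptprb at −2.12 (SE 0.263). Of 12 neutrophil markers 3 were tested and all were higher (3 adjusted over the list alone, camera adjusted p = 0.00014, adjusted p = 0.178 with an estimated correlation), among them Lcn2, an iron-siderophore binding protein (4.29, SE 0.221), and Camp, an antimicrobial peptide gene (3.89, SE 0.215).

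**Figure D4:**
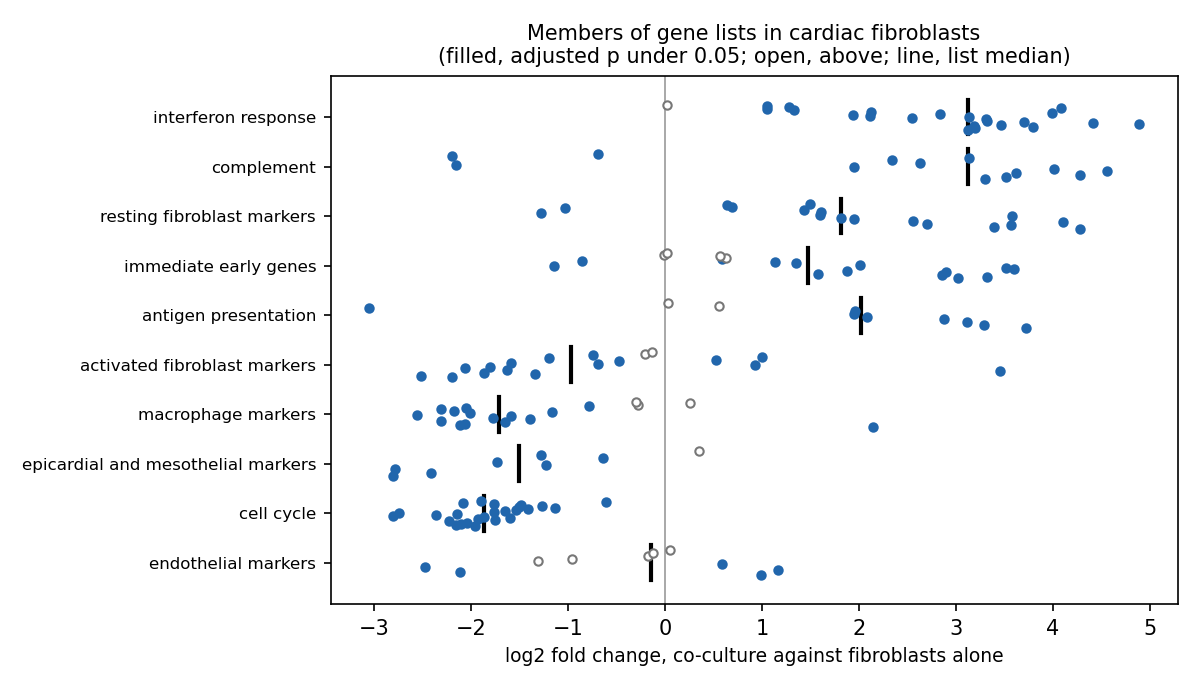
Log2 fold change of each tested member (points) of 10 gene lists (rows of the plot) in co-cultured fibroblasts against fibroblasts grown alone, n = 3 each. Filled points passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, open points did not, and vertical lines are list medians, from 3.13 for interferon response to −1.87 for cell cycle genes.

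Single genes with the highest ratios in co-culture were the chemoattractant genes Ccl19 (17.7 ± 2.12 against 0.225 ± 0.159 CPM, a log2 fold change of 6.21, or 6.86 without alone replicate 3) and Rarres2 (195 ± 29.2 against 2.70 ± 1.06 CPM). The angiotensin-converting enzyme gene Ace averaged 275 ± 24.2 CPM in co-culture and 7.14 ± 2.04 CPM alone, a log2 fold change of 5.28 (SE 0.212, adjusted p = 8.88e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Oas1a (4.89) and Oas1g (5.58), antiviral oligoadenylate synthetase genes, were also higher, but they are near-identical copies, so their split is uncertain. Among the lowest ratios were Mki67, the proliferation marker Ki-67 (2.78 ± 0.278 against 18.7 ± 4.25 CPM), and the imprinted long non-coding RNA Meg3 (6.31 ± 0.822 against 44.9 ± 4.59 CPM).

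Fap was low in both cultures, with 14 to 16 counts per library in co-culture and 19 to 32 alone, or 3.20 ± 0.508 and 1.58 ± 0.279 CPM. The difference of 1.00 passed the test (SE 0.288, adjusted p = 0.0152, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) but not without co-culture replicate 2 (0.90, adjusted p = 0.0599), without alone replicate 3 (0.87, 0.0591) or with total-count scaling (0.65, 0.104), with a range over 17 settings of 0.00155 to 0.104. Dpp4 was lower in co-culture, at 1.94 ± 0.517 against 7.36 ± 2.05 CPM (−1.95, SE 0.322, edgeR adjusted p = 0.000838). Nppb was too low to test, with 0 counts in each co-culture library and 4, 1 and 5 counts alone, and 3 counts correspond to 0.524 to 0.727 CPM per co-culture library.

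Between the cultures 7351 of 12293 genes were called (3729 higher, 3622 lower, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the groups did not overlap for 67.0% of genes, where chance gives 10%. Total-count scaling moved the share of called genes that were higher from 50.7% to 32.7% and the median log2 fold change of all genes from −0.06 to −0.41. In alone replicate 2 a single gene, the actin gene Actb, held 18.5% of the counts, against 3.13% to 5.81% in the other 5 libraries.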

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

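The splits of libraries, the count of genes on or off in 1 group and the test of Nnt were fixed before their results were seen. So were the direct comparison of inhibitor with knockout hearts and the fit with the cardiomyocyte marker level as a covariate. The other tests in this part, and the use of that fit to weigh explanations, were chosen afterwards.

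A total of 311 groups of 4 hearts were searched for 1 heart far from the other 3. Of these 21 had one, where chance gives about 1 in 20, or 15.6. MI replicate 3 held 10 of the 21, and also had the highest cardiomyocyte marker level of the MI hearts (9.32, others 7.95 to 8.33) and the highest mitochondrial share (8.03%, others 4.18% to 5.28%). The cause was not tested. MI replicate 3 was highest in the cardiomyocyte stress level (7.39, others 6.20 to 6.37), the natriuretic peptide and cGMP signalling level (2.98, others 2.49 to 2.52) and 8 genes in CPM. These were Abra (30.6, others 6.68 to 8.71), Ankrd1 (3950, others 1850 to 2150), Car14 (7.59, others 3.28 to 3.74), Cox7a1 (1090, others 555 to 612), Cox8b (1030, lowest 489), Myl3 (1530, others 482 to 604), Ppara (2.92, others 1.70 to 1.76) and Tuba8 (8.62, others 3.12 to 3.47). MI replicate 2 was highest in the neutrophil granule genes Camp (86.9, others 7.33 to 16.6) and Ngp (55.4, others 3.13 to 10.9).

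Among inhibitor hearts, replicate 4 was lowest in the interferon response level (4.89, others 5.11 to 5.15) and highest in Lamb3 (4.79 CPM, others 2.84 to 3.17). Replicate 1 was highest in Junb (102 CPM, others 87.0 to 89.5) and replicate 3 in Slfn1 (14.9 CPM, others 10.3 to 11). Among knockout hearts, replicate 4 was highest in Dpp4 (1.75 CPM, others 0.816 to 0.958) and lowest in Lamb3 (3.86 CPM, others 8.16 to 8.79). Replicate 1 was highest in Ifi213 (7.30 CPM, others 5.45 to 5.69) and Npr2 (9.92 CPM, others 7.80 to 7.92), and replicate 3 in Pkd2l2 (20.3 CPM, others 10.1 to 11.5).

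The changes from MI hearts differed between inhibitor and knockout hearts for 2247 genes by edgeR's quasi-likelihood test. Fap differed by 1.93 and Mme by −1.41 on the log2 scale. The median difference was 1.20 for interferon response genes, 0.69 for activated fibroblast markers, 0.55 for immediate early genes, −0.76 for fatty acid oxidation genes and −1.59 for adipocyte markers.

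Chance as the source of the calls was tested by regrouping the libraries. In each heart comparison 1 of 35 splits, the real one, called as many genes as the labels did. This is the smallest share that 35 splits allow, and it was not adjusted over the comparisons. Splits that mix the groups also put the group difference into the spread, which lowers their counts. The labels thus gave the highest count each time, but chance was not excluded. The real and highest other counts were 11783 and 8272 for MI against sham, 5081 and 1684 for inhibitor against MI, 8700 and 0 for knockout against MI, 2247 and 0 for inhibitor against knockout, 9517 and 7030 for inhibitor against sham, and 6740 and 4296 for knockout against sham. In the fibroblasts 1 of 10 splits called as many, with 7351 and 0, and 10 splits are too few for a share under 0.05.

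Most genes called in inhibitor and knockout against MI hearts lost their call with the cardiomyocyte marker level as a covariate. That level did not overlap between the groups compared (7.95 to 9.32 in MI, 9.73 to 10.6 in inhibitor and 10.4 to 10.7 in knockout hearts). The covariate thus separates it from the group only in part, and lost calls do not show that the genes follow the level. A larger share of cardiomyocyte RNA alone would leave endothelial and macrophage markers in proportion. In knockout hearts their difference rose by 1.32 (exact permutation p = 0.0286), which argues against a larger cardiomyocyte share alone there. In inhibitor hearts it was 0.593 and did not pass (exact permutation p = 0.0571). The difference between endothelial and adipocyte markers rose by 2.00 in inhibitor hearts (exact permutation p = 0.0286) and by 0.874 in knockout hearts (p = 0.0857). Adipocyte markers were chosen after they had been seen to be lower in inhibitor hearts. The endothelial and macrophage pair was also chosen after the results were seen. The p of 0.0286 is the smallest these group sizes allow, and it was not adjusted over these tests. A larger cardiomyocyte share alone was therefore not excluded in either group. Less infarcted tissue in the piece sampled would give the same picture as better preserved muscle. With the level as a covariate, the median absolute log2 fold change of called genes was 0.309 of its size in inhibitor and 0.391 in knockout hearts. Of these genes 71% and 74% kept their direction. The medians with the covariate (0.205 and 0.309) lay below the median standard errors (0.251 and 0.314). Less infarcted tissue and better preserved muscle cannot be told apart, because the piece sampled and the group are not separated by design.

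Interferon response genes were lower in knockout than in MI and inhibitor hearts. If fewer macrophages were the only cause, interferon response genes would differ by no more than macrophage markers. Between inhibitor and knockout hearts they differed by 0.636 more per heart, which did not pass by itself (2-sided exact permutation p = 0.0571). With the macrophage marker level of each heart as a covariate, the interferon median was 1.25 in inhibitor against knockout hearts (1.20 without, 22 of 24 genes called) and −1.47 in knockout against MI hearts (−1.44 without, 19 of 24 called). Macrophage markers moved to a median of 0.15 from 0.67 and to −0.25 from −1.26. These markers form the covariate, so their move was largely built in and is no check of it. Over all genes, the calls fell with this covariate from 2247 to 200 and from 8700 to 231. Interferon response genes thus did not follow the macrophage marker level in these fits. The level itself differs between the groups, so a covariate separates it from the group only in part. Fewer macrophages alone was therefore not excluded, and a different state of the macrophages or of other cells stays open. Ifih1, a viral RNA sensor gene beside Fap, was singled out after its values were seen. In knockout hearts it differed from sham by 0.0762 on the log2 scale (SE 0.108). A loss of its mRNA by 1 log2 unit or more below sham could thus be excluded. Sham hearts had no infarction, so a smaller rise of Ifih1 after MI was not excluded. Ifih1 averaged 6.67 CPM in knockout, 15.8 in MI and 14.8 in inhibitor hearts. Whether this lower level is a cause or a part of the pattern was not tested. Another strain background was tested by genes on or off in knockout hearts alone, and 0 were found, but also 0 in sham, MI and inhibitor hearts, so the test could not decide. A looser test found 1 gene at least 4-fold apart from every other heart, Gm14719 (34.5 CPM, others at most 1.93), against 0 in inhibitor and 0 in MI hearts. Sham hearts had 18, but they also differ from all other hearts in having no infarction, so their number is no measure of strain. As 1 gene is too few to decide, strain cannot be told apart from the loss of Fap.

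Sham hearts held counts on a nuclear copy of a mitochondrial gene that the other hearts nearly lacked. The copy Gm28438, chosen after its values were seen, averaged 1230 ± 264 CPM in sham and 16.6, 12.7 and 19.3 CPM in MI, inhibitor and knockout hearts. It is identical to mt-Nd3 at 344 of 345 bases (99.7%), with the mismatch at base 3 of mt-Nd3, so reads can be placed on either gene. The level of mt-Nd3 itself (31.5 ± 12.1 CPM in sham, 285 ± 64.1 in knockout) is therefore uncertain. This identity is the same for every heart, so shared reads alone do not explain why only sham hearts held these counts. Another substrain of the sham mice was tested with Nnt, which lay at −0.28 (SE 0.21) between knockout and sham hearts. The range of 40 oxidative phosphorylation genes was −1.27 to −0.69. Nnt lay outside this range by less than 2 standard errors, so the test could not decide and another substrain stays open. Beyond the substrain, no biological explanation of these sham counts was tested.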

How the results depend on the processing

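Of 278 gene results followed, all had the same call with a filter of 1 CPM in 3 libraries, and 277 with DESeq2, RLE or the replicate block, 276 with limma-voom and 275 with GC and length trends removed. An absolute log2 fold change of at least 1 left 265 of the 278 with the same call, total-count scaling 255 (16 stronger, 4 weaker, 3 turned) and the cardiomyocyte covariate 157 of 232 (71 weaker, 1 stronger, 3 turned). Leaving out 1 library gave 1980 of 2012 values the same call. Total-count scaling and GC, length and depth corrections were chosen after the results were seen. A fit of the series-wide table, fixed before the data were examined, was not run, because its columns map to no label.

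Requiring an absolute log2 fold change of at least 1 leaves fewer genes by construction: 4215 in fibroblasts, 6895 for MI against sham, 1448 for inhibitor against MI, 3218 for knockout against MI, 552 for inhibitor against knockout, 4340 for inhibitor against sham and 2028 for knockout against sham. With the cardiomyocyte marker level as a covariate the counts were 1292 for MI against sham, 30 for inhibitor against MI, 143 for knockout against MI and 5782 for inhibitor against sham. Median standard errors rose from 0.159 to 0.251 for inhibitor and from 0.157 to 0.314 for knockout against MI, so part of the loss lies in precision. Total-count scaling called 9933 for inhibitor against MI, and the cause was not tested. Leaving out 1 library gave 3359 to 5495 for inhibitor against MI (5081 with all) and 1125 to 2920 for inhibitor against knockout (2247 with all). These fits have fewer samples by construction, which does not account for the counts above those with all libraries. The cause was not tested.

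Among results called in at least 1 of the 2 fits compared, the direction turned for 6, and the cause was not tested. It also turned in 48 values of 16 results that were called in neither. The 6 were, with the covariate, Iglc3, an immunoglobulin gene with near-identical copies, in MI against sham (−1.52, adjusted p = 0.662, range 1.02e-08 to 0.662), Fap in inhibitor against MI (0.13, 0.981, range 0.00239 to 0.981) and Col5a1 there (0.0524, 0.993, range 0.000204 to 0.993). With total-count scaling they were Npr1 in knockout against MI (−0.52, 0.0292, range 0.0292 to 1), and Irf9 (0.14, 0.392, range 0.000589 to 0.392) and Gbp3 (0.10, 0.624, range 0.00138 to 0.624) in knockout against sham.

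Of the lists fixed in advance, camera with an estimated correlation called 0 in fibroblasts, 0 for MI against sham and 0 for inhibitor against MI. It called 1 for knockout against MI, 1 for inhibitor against knockout, 0 for inhibitor against sham and 0 for knockout against sham. The fry test called 30 of these lists for MI against sham. With separate MI hearts the correlation of inhibitor and knockout changes was 0.686, and 86.5% and 93.3% of genes moved toward sham. Among genes past 2-fold after MI these shares were 93.5% and 98.1%.

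Replicate numbers do not pair the samples in the labels. Same-numbered libraries deviated together with a mean r of −0.0683 over 3 pairs in fibroblasts (−0.183 to 0.0643) and 0.0537 over 21 pairs in hearts (−0.294 to 0.322). With the replicate block 6862 genes were called in fibroblasts, 11687 for MI against sham, 4968 for inhibitor against MI, 8630 for knockout against MI, 2035 for inhibitor against knockout, 9395 for inhibitor against sham and 6662 for knockout against sham. It changed 1 named call, Dpp4 in knockout against sham (−0.96, adjusted p = 0.0379). Fibroblast libraries thinned to equal totals called 6479 of 10890 genes tested.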

Other observations

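The 4 gene lists in this part were added after the gene results had been seen, and so were their tests, so their p-values do not carry the weight of those of lists fixed in advance. Genes induced by peroxisome proliferator-activated receptors (PPAR), which drive fatty acid use, were lower in inhibitor than in knockout hearts in 12 of 17, and 5 did not pass the test (median log2 fold change −0.97, 16 adjusted over the list alone, camera adjusted p = 2.38e-23, adjusted p = 0.000548 with an estimated correlation). The glycerol channel gene Aqp7 was lower by −2.16 (SE 0.183). In knockout against MI hearts 13 of these 17 rose and 4 did not pass (median 1.83, 13 adjusted over the list alone, camera adjusted p = 1.31e-14, adjusted p = 0.00362 with an estimated correlation). After MI 13 fell, 3 rose and 1 did not pass (median −2.74, camera adjusted p = 3.34e-07, adjusted p = 0.046 with an estimated correlation).

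Glucocorticoid-induced genes were higher in inhibitor than in knockout hearts in 10 of 17, and 7 did not pass (median 0.63, 11 adjusted over the list alone, camera adjusted p = 2.88e-11, adjusted p = 0.0135 with an estimated correlation). Examples were the transcription factor gene Cebpd (1.44, SE 0.149) and the glucocorticoid receptor partner gene Fkbp5 (1.01, SE 0.107). Against MI hearts 11 of the 17 fell in knockout hearts, 2 rose and 4 did not pass (median −0.86, camera adjusted p = 0.00031, adjusted p = 0.184 with an estimated correlation). In co-cultured fibroblasts 14 of 16 were higher and 2 lower (median 2.39, camera adjusted p = 1.98e-12, adjusted p = 0.0628 with an estimated correlation). Circadian clock genes were lower in knockout than in sham hearts in 14 of 18, higher in 3 and not past the test in 1 (median −0.65, camera adjusted p = 0.000336, adjusted p = 0.0664 with an estimated correlation), with Ciart at −1.27 (SE 0.165). This was not particular to the knockout, since the level of the list was 3.81 ± 0.0944 in sham, 3.14 ± 0.0783 in MI, 3.38 ± 0.0846 in inhibitor and 3.34 ± 0.0558 in knockout hearts. Plasma cell and immunoglobulin genes were higher in knockout than in sham hearts in 5 of 12, and 7 did not pass (median 2.17, camera adjusted p = 0.00507, adjusted p = 0.341 with an estimated correlation), and many of them have near-identical copies that share reads.

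The nuclear gene Gm10222, chosen after its values were seen, is identical to mt-Nd4l over 294 of 294 bases. It averaged 21.3 ± 3.10 CPM in sham, 0.391 ± 0.105 in MI, 0.754 ± 0.166 in inhibitor and 1.46 ± 0.152 in knockout hearts, and mt-Nd4l itself held 0 or 1 counts in every heart.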
